A study of Arabidopsis thaliana with 20 samples.

How the data were processed

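The deposited values are MAS5 signal intensities, as deposited by the authors, on the linear scale and in 1 table of 22810 probe sets and 20 arrays. Per the labels, total RNA was extracted with RNeasy and biotinylated cRNA was made by the standard Affymetrix protocol. The MAS5 version and its scaling target are not given in the sources used here. All replicate 1 arrays have a trimmed mean (2% trimmed) of 310.9 and all replicate 2 arrays 236.9, which is 0.39 on the log2 scale, and this was left as deposited in the main analysis.

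Groups were taken from the sample titles and labels. The 64 control probe sets were left out. Of the other 22746, 15469 were tested, those with a group mean above the 40th percentile of all values (6.553 on the log2 scale) in at least 1 of the 10 groups. The filter left out 7277. Values were analysed as log2 of the signal plus 27.39, which is 0.1 of the median trimmed mean, in 1 fit of 10 group means over all arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend). The residual degrees of freedom were 10 and the median prior degrees of freedom 9.46, against 9 and 5.95 with the replicate number as a block. P-values were adjusted by Benjamini-Hochberg within each comparison and called below 0.05. Differences between mutants and wild type in a response are interaction contrasts of the same fit.

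Named genes follow a rule: the 8 genes with the largest positive and the 8 with the largest negative log2 fold change in each main comparison, and 3 of each in the others, among called probe sets that map to exactly 1 gene and whose arrays do not overlap between the groups. In addition the signal of the higher group had to lie above the median of 115. For interactions the non-overlap was taken as the same sign in both replicates. Members of gene lists that passed were named beside these, and any other gene is said to have been chosen after its values were seen. AT4G29020 and ARR15 are followed through all groups, the former because the rule named it in several comparisons. Of the probe sets, 13513 map to 1 gene in the array's name table, 503 to several and 8730 to none, and 1580 carry a name other than a locus tag. The probe sets of CKH1 and CKH2 could not be named, so their own transcripts are not reported here.

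Gene lists were tested with limma's camera (preset correlation of 0.01) and, as alternatives, with an estimated correlation and with fry, for lists with at least 3 tested members. Without the block, the residuals that give the estimated correlation include the scaling difference between replicate numbers. A list that fails there is therefore not shown to be unchanged. Of the 24 lists fixed before the data were examined, with 274 entries, 32 entries were named on the array and only the auxin response and photosynthesis lists reached 3 tested members. A further 22 lists were written once the probe names were known and before any test.

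The alternatives were quantile normalization, no filter, a pseudocount of 2.739, which is 0.01 of the trimmed mean, the replicate block, and each array of the compared groups left out in turn. With 1 array left out its group has 1 array, which is assumed to vary like the others. Unless stated, such fits had no block, so the scaling was then unbalanced between the compared groups. A lost call or a lower total there can therefore come from the scaling as well as from the array or from fewer arrays. The design, the named-genes rule and these alternatives were set before the data were examined. Rescaling all arrays to a common trimmed mean, the block together with 1 array left out, and the list tests with the block were chosen after seeing the data. The blocked counts had been seen when it was decided to print them beside the others. Alternatives used the probe sets of the main filter, except that no filter and the smaller pseudocount set their own.

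The procedure was tested on simulated data with 200 changed of 15469 probe sets. For a comparison of 2 arrays with 2 it recovered 20 of 100 at a log2 change of 1 and 94 of 100 at a log2 change of 2 with 1 unchanged probe set called, and with the block 81 and 99 with 5 unchanged. For 6 arrays against 6 it recovered 97 and 100 with 4 unchanged called, and with the block 99 and 100 with 13. A simulated list of 20 shifted by 0.8 had a camera p of 1.09e-51 over all probe sets, and an unshifted one 0.636. Apart from the replicate shift, simulated probe sets varied independently, so this does not test the preset correlation for real lists. A single unshifted list also gives no rate of false calls.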

Results

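Gene expression was measured on 20 Affymetrix arrays of hypocotyl segments from Arabidopsis thaliana, in 10 groups of 2 arrays each. The segments came from seedlings grown for 10 days in dim light and were held for 3 days on callus induction medium, which contained the auxin 2,4-D at 100 ng/ml. The wild type (Ler) and the mutants ckh1-1 and ckh2-1 were each given the cytokinin kinetin at 0, 25 or 200 ng/ml. The remaining wild type group received no kinetin and TSA (trichostatin A, an inhibitor of histone deacetylases) at 100 ng/ml. The series title asks how the CKH1 and CKH2 genes affect cytokinin responses in tissue culture. Median signal per array ran from 92.6 to 137 and the summed signal from 6796485 to 9253461. Within each group, the log2 values of both arrays correlated across probe sets with r from 0.958 to 0.987. All replicate 1 arrays had a trimmed mean signal of 310.9 and all replicate 2 arrays 236.9, a ratio of 1.31. This scaling split is balanced over the groups, so counts from a fit with the replicate number as a block are printed beside the main ones. Within a replicate number each group has 1 array, so that fold changes can be given there and tests cannot. Nothing in the labels says that the replicates are separate cultures, and the p-values measure only the spread between these arrays. Without the block that spread includes the scaling difference between replicate numbers. For 2 arrays against 2 the median SE was 0.289 without the block and 0.169 with it. The number of arrays limits the precision. Fold changes are on the log2 scale with their SE and compare 2 arrays with 2 unless stated, and signals are means with SD (n = 2). The SD of a deposited signal includes the scaling difference between replicate numbers.

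Among the genes that the rule names, OCT1, a membrane transporter of organic cations, rose in wild type at 200 ng/ml kinetin by 3.70 ± 0.44, from a signal of 45.1 ± 58.8 to 865 ± 625. Of its arrays without kinetin, replicate 2 was near the floor (3.56), so the size of this change and its rank depend on the pseudocount. ALPHA-VPE, a vacuolar processing enzyme, rose by 2.99 ± 0.45, and the chitinase family gene AT2G43620 by 2.54 ± 0.52. AT3G61920, AT2G01610, AT1G62480, AT1G03620 and AT5G19100 rose by 2.36 to 2.61. AT4G38080 fell by 2.94 ± 0.32, and the GDSL lipase family genes AT2G23540 and AT1G74460 had log2 fold changes of -2.88 ± 0.31 and -2.36 ± 0.44. AT3G22620, AT1G69526, AT2G22510 and ZW9 had log2 fold changes from -2.87 to -2.30, and the class III peroxidase gene AT4G08780 fell by 2.13 ± 0.24. Adjusted p for these 16 genes ran from 2.64e-05 to 0.00835 (limma, Benjamini-Hochberg). Of them, 13 stayed past the threshold under every alternative. The calls of AT2G43620 (adjusted p = 0.187) and ZW9 (adjusted p = 0.142) were lost without replicate 1 of wild type at 200 ng/ml, and that of AT1G74460 without replicate 1 of wild type without kinetin (adjusted p = 0.0858).

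Cell wall loosening genes went both ways in this comparison. Of 18 expansins and xyloglucan endotransglucosylases, 3 rose and 3 fell, or 4 and 6 adjusted over the list alone. XTH32 rose by 1.79 ± 0.27 and EXPB3 by 1.45 ± 0.28, while XTH19 fell by 1.90 ± 0.35 and EXLB1 by 1.61 ± 0.29. The calls of EXPB3 (adjusted p = 0.0878), XTH19 (adjusted p = 0.0667) and EXLB1 (adjusted p = 0.0918) were lost without replicate 1 of wild type, at 200 ng/ml for EXPB3 and without kinetin for the others. IRX15-L, which acts in xylan formation, was the 1 of 7 secondary wall genes that rose (0.98 ± 0.23), or 4 adjusted over the list alone, and its call was lost without replicate 1 of wild type without kinetin (adjusted p = 0.239). That list lay higher by camera (adjusted p = 0.0317), but not with the correlation taken from the data (adjusted p = 0.888 with an estimated correlation). None of the 33 nuclear photosynthesis and chlorophyll genes passed limma's test, 0 adjusted over the list alone and 3 higher with the block. Their median was 0.27 (camera adjusted p = 0.000902, and adjusted p = 0.888 with an estimated correlation). BBM, an AP2 family factor known from embryogenesis, fell by 1.45 ± 0.31 (adjusted p = 0.0124, and 0.243 without replicate 1 of wild type without kinetin). Neither of the gene lists fixed beforehand with enough members, auxin response and photosynthesis genes, had a member past the test in wild type at 200 ng/ml. Adjusted over the list alone, 1 of 6 auxin response genes was lower and 0 of 3 photosynthesis genes changed, and camera gave adjusted p = 0.247 and 0.231.

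In all, limma called 255 probe sets higher and 219 lower at 200 ng/ml in wild type, of which 248 map to 1 gene and 220 to no gene in the name table. With the replicate block it called 874 higher and 890 lower. Every called probe set had the same sign in both replicate numbers, which their selection on these same arrays made likely. Fold changes over all 15469 tested probe sets correlated between replicate numbers with r = 0.519. Without replicate 1 of wild type at 200 ng/ml the total was 148, and without replicate 1 of wild type without kinetin it was 182.

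The wild type had no call at 25 ng/ml. ARR15 had signals of 50 ± 5.53 at 25 ng/ml and 24.8 ± 0.145 without kinetin, against 48.7 ± 10.2 and 26.6 ± 29.4 in ckh1-1 and 56.7 ± 9.07 and 27.6 ± 3.65 in ckh2-1. Of 15469 probe sets, 243 had an unadjusted limma p below 0.05, fewer than chance alone would give, and 881 with the replicate block. limma with Benjamini-Hochberg adjustment called 0 probe sets, and the fit with the replicate block called 8 higher and 2 lower. Quantile normalization, rescaled arrays, no filter and the smaller pseudocount also gave 0, and leaving out replicate 1 of wild type without kinetin gave 1.

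ARR15, a type-A response regulator induced by cytokinin, is the only tested member of that class with a name in the table. At 200 ng/ml it rose by 1.83 in wild type (adjusted p = 0.00608), by 1.73 in ckh1-1 (adjusted p = 0.0026) and by 2.05 in ckh2-1 (adjusted p = 0.000629). Signals without kinetin and at 200 ng/ml were 24.8 ± 0.145 and 174 ± 113 in wild type, 26.6 ± 29.4 and 141 ± 47.4 in ckh1-1, and 27.6 ± 3.65 and 201 ± 30.8 in ckh2-1. The difference in ARR15 response between mutant and wild type was -0.10 for ckh1-1 (adjusted p = 0.999) and 0.22 for ckh2-1 (adjusted p = 1). The ARR15 call was lost in wild type without its replicate 1 at 200 ng/ml (adjusted p = 0.177) and in ckh1-1 without its replicate 2 without kinetin (adjusted p = 0.0811). RR16, of the same class, was too dim to be tested: its wild type signal was 5.02 ± 5.97 without kinetin and 58.3 ± 9.99 at 200 ng/ml. In ckh1-1 these signals were 10.9 ± 12.9 and 25.4 ± 0.903, and in ckh2-1 12.7 ± 0.547 and 40.7 ± 0.761. UGT76C2, which glucosylates cytokinins, fell by 1.18 in ckh1-1 at 200 ng/ml (adjusted p = 0.0178). Its fold change was -0.58 in wild type (adjusted p = 0.581), and the difference between them did not pass (-0.60, adjusted p = 0.999). The UGT76C2 call in ckh1-1 was lost without its replicate 2 at 200 ng/ml (adjusted p = 0.122).

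In ckh1-1, kinetin at 200 ng/ml raised AT4G30650 by 3.74 ± 0.38, AT4G33550 by 3.69 ± 0.36 and the amine oxidase gene AT1G31710 by 3.36 ± 0.28. AT4G29020 fell by 5.51 ± 0.29, from 4670 ± 532 to 75.4 ± 0.509, AT5G45670, of the GDSL lipase family, by 5.41 ± 0.37, and AT4G21620 by 5.01 ± 0.35. The signal of AT5G45670 at 200 ng/ml was near the floor (6.1 ± 0.549), so the size of its change and its rank depend on the pseudocount. Of 6 auxin response genes 3 fell, also 3 adjusted over the list alone, with a median of -1.23. They were GH3.1 (-2.93 ± 0.41) and WES1 (-2.39 ± 0.37), which conjugate auxin to amino acids, and LBD16 (-2.65 ± 0.34), a factor of lateral root formation. Camera called this list lower (adjusted p = 0.0104), but not with the correlation taken from the data (adjusted p = 0.612 with an estimated correlation). The lateral root factor PUCHI fell by 2.36 ± 0.24, BBM by 3.07 ± 0.31 and the seed bZIP factor EEL by 1.85 ± 0.35. Of 7 secondary wall genes 3 rose, or 4 adjusted over the list alone: IRX15 by 1.85 ± 0.26, IRX15-L by 1.77 ± 0.23 and TBL34 by 1.25 ± 0.27 (camera adjusted p = 0.00299, and adjusted p = 0.612 with an estimated correlation). Of 33 nuclear photosynthesis and chlorophyll genes 6 rose, also 6 adjusted over the list alone and 16 with the block, among them the photosystem II subunit PSBW by 1.44 ± 0.33 (camera adjusted p = 7.8e-05, and adjusted p = 0.622 with an estimated correlation). TBL34 and PSBW lost their calls without replicate 1 of ckh1-1 without kinetin (adjusted p = 0.0817) and without replicate 1 of ckh1-1 at 200 ng/ml (adjusted p = 0.063) respectively. Of the photosynthesis list RCA alone passed, 2 of 3 adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.612 with an estimated correlation); its call was lost without replicate 1 of ckh1-1 at 200 ng/ml (adjusted p = 0.174). limma called 816 probe sets higher and 883 lower, 841 of them mapping to 1 gene, and the block gave 2248 and 2897. Fold changes correlated with r = 0.836 between replicate numbers, and leaving out single arrays gave totals from 1030 to 1183.

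The lower dose gave calls in ckh1-1 where the wild type had none. AT3G45160 rose by 2.53 ± 0.34, AT4G23670 by 2.45 ± 0.43 and AT4G33550 by 2.45 ± 0.36. The GDSL lipase family gene AT1G75880 fell by 3.06 ± 0.33, ZW9 by 2.57 ± 0.45, and AT1G29670, of the same lipase family, had a log2 fold change of -2.30 ± 0.55. AT4G29020 fell by 1.53 (adjusted p = 0.00689). IRX15 and IRX15-L rose by 1.08 ± 0.26 and 0.97 ± 0.23, the 2 of 7 secondary wall genes that passed, or 3 adjusted over the list alone (camera adjusted p = 0.0047, and adjusted p = 0.67 with an estimated correlation). limma called 181 probe sets higher and 118 lower, and the block gave 855 and 616, with r = 0.739 between replicate numbers. The total was 68 without replicate 1 and 129 without replicate 2 of ckh1-1 without kinetin, and 103 and 87 without those at 25 ng/ml. The calls of ZW9 (adjusted p = 0.0938), AT1G29670 (adjusted p = 0.301), IRX15 (adjusted p = 0.287) and IRX15-L (adjusted p = 0.241) were each lost under at least 1 alternative, and these are their highest values.

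In the test of the difference itself, ckh1-1 against wild type in the response to 200 ng/ml, AT4G38080, AT1G74460 and AT2G23540 had higher responses in ckh1-1 by 4.09 ± 0.46, 3.80 ± 0.62 and 3.76 ± 0.43. These fell in wild type. AT4G29020, AT5G45670 and AT5G01870 had lower ones, by -4.46 ± 0.41, -4.36 ± 0.52 and -3.76 ± 0.43. Higher and lower give only the sign of the difference, so a lower response can be a larger fall or a smaller rise. AT4G29020 fell in both genotypes, and further in ckh1-1. For AT5G45670 the size depends on the pseudocount, as its ckh1-1 signal at 200 ng/ml was near the floor. None of the 6 auxin response genes differed over all probe sets tested, and 3 were lower adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.49 with an estimated correlation). limma called 48 probe sets with a higher response and 141 with a lower one, and the block gave 373 and 447, so that the higher share moved from 25.4% to 45.5%; it was 43.2% after quantile normalization and 40.5% after rescaling. Totals with 1 array left out ran from 111 (replicate 2 of ckh1-1 at 200 ng/ml) to 212, with 124 and 121 without replicate 2 of wild type without kinetin and at 200 ng/ml and 117 without replicate 1 of ckh1-1 without kinetin. For the response to 25 ng/ml the only call was a probe set that has no gene name in the table and was singled out after its values were seen. Its difference was -2.53 ± 0.37 (adjusted p = 0.0241). The block called 107 higher and 51 lower, quantile normalization 84 in total and rescaled arrays 90, while no filter and the smaller pseudocount gave 0.

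In ckh2-1, kinetin at 200 ng/ml raised AT1G12080 from a signal of 117 ± 63.5 to 1540 ± 291, AT4G33550 by 3.45 ± 0.36 and AT5G11420 by 3.45 ± 0.34. AT4G29020 fell by 4.08 ± 0.29, AT1G73620 by 4.03 ± 0.36 and AT5G48940 by 3.83 ± 0.33. Of 6 auxin response genes 4 fell, also 4 adjusted over the list alone: LBD16 by 1.66 ± 0.34, GH3.1 by 1.59 ± 0.41, LBD29 by 1.43 ± 0.44 and WES1 by 1.24 ± 0.37. Each of these calls was lost under at least 1 alternative, with highest adjusted p of 0.0753, 0.272, 0.348 and 0.282. Camera called the list lower (adjusted p = 0.0128), but not with the correlation taken from the data (adjusted p = 0.603 with an estimated correlation). PUCHI fell by 2.15 ± 0.24 and BBM by 2.84 ± 0.31. Of 7 secondary wall genes 3 rose, or 4 adjusted over the list alone: IRX15-L by 1.69 ± 0.23, IRX15 by 1.60 ± 0.26 and TBL34 by 1.58 ± 0.27 (camera adjusted p = 0.00334, and adjusted p = 0.495 with an estimated correlation). Beta-glucosidases BGLU47 and BGLU33 rose by 2.35 ± 0.30 and 1.86 ± 0.25. limma called 626 probe sets higher and 654 lower, the block 1809 and 2038, with r = 0.856 between replicate numbers. The total was 727 without replicate 1 of ckh2-1 at 200 ng/ml, and 847 and 743 without replicates 1 and 2 of ckh2-1 without kinetin.

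In ckh2-1, 25 ng/ml gave 14 probe sets higher and 0 lower, against 133 and 13 with the block. An unadjusted limma p below 0.05 was reached by 578 of 15469, fewer than chance alone would give, and by 1845 with the block. AT5G40020 rose by 2.08 ± 0.27, the class III peroxidase family gene AT5G51890 by 1.90 ± 0.30 and AT4G33550 by 1.90 ± 0.36. All of these 3 calls were lost with single arrays left out (highest adjusted p of 0.209, 0.436 and 0.984), and the total fell to 0 without replicate 2 of ckh2-1 without kinetin or replicate 1 at 25 ng/ml; it was 4 and 7 without the others. Fold changes correlated with r = 0.164 between replicate numbers.

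The response to 200 ng/ml was higher in ckh2-1 than in wild type for AT2G30540, a glutaredoxin family gene (2.99 ± 0.33), AT1G12080 (2.71 ± 0.43) and the plastid gene psbT (2.11 ± 0.42). It was lower for OCT1 (-3.67 ± 0.63), AT4G17350 (-3.05 ± 0.56) and AT4G29020 (-3.04 ± 0.41). Lower is again only a sign: OCT1 rose in wild type, while AT4G29020 fell in both genotypes and further in ckh2-1. OCT1 was near the floor in ckh2-1 at every level, so its difference depends on the pseudocount and gives only a direction. The calls of psbT, OCT1 and AT4G17350 were lost under at least 1 alternative, with highest adjusted p of 0.169, 0.166 and 0.114. None of the 6 auxin response genes differed, also 0 adjusted over the list alone (camera adjusted p = 0.0316, and adjusted p = 0.576 with an estimated correlation). limma called 7 probe sets with a higher response and 49 with a lower one; the block gave 91 and 178, and the higher share moved from 12.5% to 33.8%, 29.8% after quantile normalization and 32.5% after rescaling. With 1 array left out the total ran from 15 to 83, both from the arrays of wild type without kinetin; it was 33 and 21 without those of wild type at 200 ng/ml, 19 and 35 without those of ckh2-1 without kinetin, and 32 and 21 without those of ckh2-1 at 200 ng/ml. For 25 ng/ml limma had 178 probe sets at an unadjusted p below 0.05, fewer than chance alone would give, and 888 with the block. After adjustment it called 0, and quantile normalization, rescaled arrays, no filter and the smaller pseudocount also gave 0. The block called 1, a probe set with no gene name in the table, singled out after its values were seen (1.58, adjusted p = 0.0477 with the block).

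**Figure D1:**
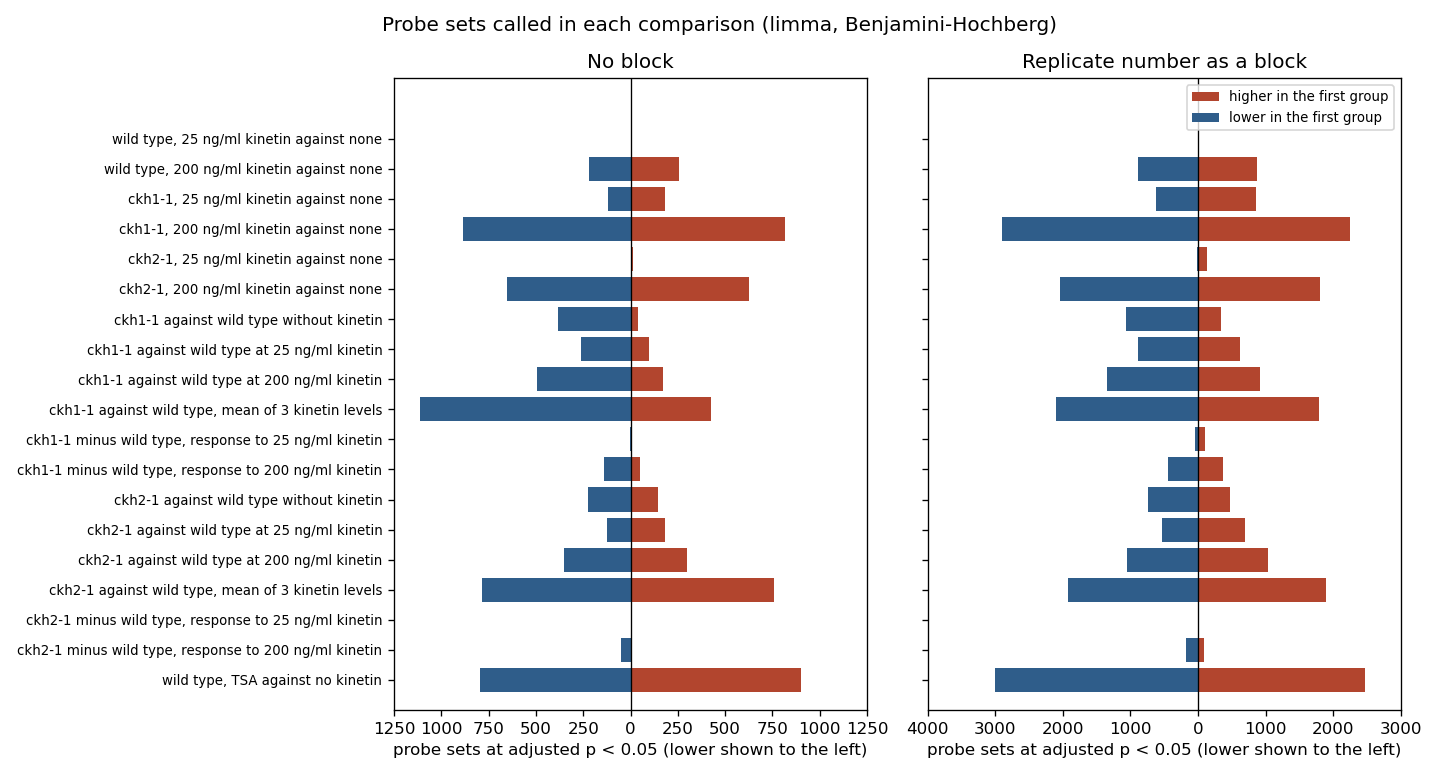
Probe sets past adjusted p of 0.05 in each comparison (limma, Benjamini-Hochberg), higher to the right and lower to the left, without and with the replicate number as a block; the axes of both panels differ in scale. The wild type had 0 calls at 25 ng/ml kinetin and 474 at 200 ng/ml without the block, against 299 and 1699 in ckh1-1 and 14 and 1280 in ckh2-1.

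Responses over a whole set of probe sets were read on arrays rescaled to a common trimmed mean, with the set taken from the deposited values. Over the 1280 probe sets that ckh2-1 called for 200 ng/ml, each signed by its direction there, the median response to 25 ng/ml was 0.20 in wild type (0.21 and 0.20 within replicates 1 and 2) and 0.76 in ckh1-1 (0.76 and 0.77). At 200 ng/ml these medians were 0.78 and 1.34. AT4G29020, a member of the set, had signals of 5560 ± 1140, 5190 ± 1740 and 2660 ± 172 in wild type at 0, 25 and 200 ng/ml, and of 4670 ± 532, 1630 ± 481 and 75.4 ± 0.509 in ckh1-1.

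**Figure D2:**
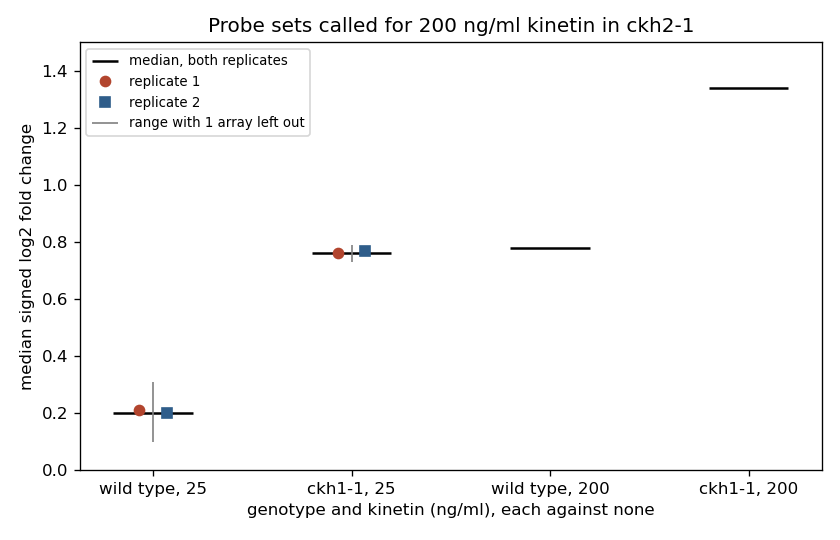
Median log2 fold change against no kinetin on rescaled arrays, signed by the direction in ckh2-1, over the 1280 probe sets called there at 200 ng/ml, for wild type and ckh1-1 at each dose (horizontal axis). Black lines are both replicates, circles and squares are replicates 1 and 2 at 25 ng/ml, gray lines the range with 1 array left out (0.10 to 0.31 in wild type, 0.73 to 0.79 in ckh1-1).

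Across the 3 kinetin levels, ckh1-1 had more transcript than the wild type of AT1G47400, a small peptide gene of the iron deficiency response, by 2.42 ± 0.21 (6 arrays against 6), with mean signals of 699 and 111. The peroxidase PRX52 was higher by 1.96 ± 0.32 and AT1G72900, which encodes a TIR domain, by 1.94 ± 0.22. AT4G26460, AT2G38870, AT1G19020, AT2G34930 and AT1G55450 were higher by 1.37 to 1.70. AT3G63360 was lower by -4.17 ± 0.34 (43.2 against 1210) and the class III peroxidase AT5G17820 by -3.65 ± 0.30. AT2G43860 was lower by -3.30 ± 0.27 and OCT1 by -3.17 ± 0.26, and AT2G33850, AT5G60530, AT3G57620 and AT3G26460 had log2 fold changes from -2.66 to -2.51. OCT1 was near the floor in ckh1-1 at every level, so the size of its difference depends on the pseudocount. Of the 16 genes, 15 stayed past the threshold under every alternative, the exception being AT2G38870 (highest adjusted p = 0.0832).

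Of 6 auxin response genes 3 were lower in ckh1-1, or 4 adjusted over the list alone, with a median of -0.67. LBD29, a lateral root factor, was lower by -1.79 ± 0.25, GH3.1 by -1.06 ± 0.24 and WES1 by -0.74 ± 0.22. Camera called the list (adjusted p = 0.00205), but not with the correlation taken from the data (adjusted p = 0.627 with an estimated correlation), and the WES1 call was lost with single arrays left out (highest adjusted p = 0.138). Of 14 serine carboxypeptidase-like genes 6 were lower, also 6 adjusted over the list alone, among them scpl20 (-1.96 ± 0.21), scpl28 (-1.34 ± 0.21) and scpl48 (-1.22 ± 0.22). Their camera call (adjusted p = 4.29e-05) gave adjusted p = 0.627 with an estimated correlation, and adjusted p = 0.0458 with an estimated correlation and the block. Of 8 glutathione transferases 4 were lower, also 4 adjusted over the list alone: GSTU27 (-1.30 ± 0.16), GSTU26 (-0.88 ± 0.17), GSTU20 (-0.88 ± 0.22) and GSTU25, whose call was lost under several alternatives (-0.56 ± 0.17, highest adjusted p = 0.189). Camera gave adjusted p = 0.00205 for them, and adjusted p = 0.627 with an estimated correlation. The sugar transporter gene SWEET2 was lower by -2.23 ± 0.21. Nuclear photosynthesis and chlorophyll genes had 4 of 33 higher, also 4 adjusted over the list alone and 15 with the block, with PSBW at 0.80 ± 0.19 (camera adjusted p = 1.67e-05, and adjusted p = 0.705 with an estimated correlation). None of the 3 genes of the photosynthesis list passed over all probe sets tested in ckh1-1, and 2 did adjusted over the list alone.

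limma called 425 probe sets higher and 1115 lower in ckh1-1 over the 3 levels, 748 of them mapping to 1 gene, with r = 0.82 between replicate numbers. The block called 1792 and 2106. The higher share was 27.6% on deposited values, 46% with the block, 47.7% after quantile normalization and 43.4% after rescaling. Lower probe sets thus stayed in the majority, and the size of their preponderance depended on how the scaling was handled. Level by level, limma called 37 higher and 383 lower without kinetin (block 344 and 1063), 99 and 262 at 25 ng/ml (block 628 and 881) and 170 and 494 at 200 ng/ml (block 918 and 1347). The higher shares of 8.81%, 27.4% and 25.6% became 24.4%, 41.6% and 40.5% with the block, 22.1%, 39.2% and 43.9% after quantile normalization and 19.7%, 36.6% and 38.8% after rescaling. With 1 array left out, the totals ran from 158 to 303 without kinetin, from 61 to 273 at 25 ng/ml and from 279 to 443 at 200 ng/ml, lowest at each level without replicate 2 of ckh1-1 and, without kinetin, equally low without replicate 1 of wild type.

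At the single levels the named genes of ckh1-1 overlapped. AT1G47400 was higher in ckh1-1 by 2.14 ± 0.36 without kinetin, 2.63 ± 0.36 at 25 ng/ml and 2.48 ± 0.36 at 200 ng/ml. AT3G63360 and AT5G17820 were lower by -4.32 ± 0.58 and -4.20 ± 0.51 without kinetin, and by -4.36 ± 0.58 and -3.79 ± 0.51 at 25 ng/ml. Without kinetin AT4G11190 was lower by -3.50 ± 0.35, and AT4G38410, a dehydrin-like gene, and AT4G26460 were higher by 1.92 ± 0.40 and 1.76 ± 0.43, calls lost without replicate 2 of wild type (adjusted p = 0.124 and 0.29). AT4G38410 was also higher at 25 ng/ml, by 2.39 ± 0.40, where OCT1 (-3.69 ± 0.44), AT2G43860 (-3.34 ± 0.46), BAT1 (-2.85 ± 0.35), AT2G33850 (-2.65 ± 0.43) and AT3G57620 (-2.50 ± 0.33) were lower. These 6 genes and AT1G47400, AT3G63360 and AT5G17820, 9 of the 16 named at 25 ng/ml, stayed past the threshold there under every alternative. The other 7 named at that level were AT4G26460 (2.32 ± 0.43), PRX52 (2.22 ± 0.56), AT4G33550 (1.97 ± 0.36), AT3G16330 (1.87 ± 0.36), AT1G72900 (1.81 ± 0.38), the expansin EXPA8 (1.80 ± 0.33) and AT1G29090 (-2.96 ± 0.49). Their calls were lost with single arrays left out, with highest adjusted p of 0.0821, 0.261, 0.0532, 0.0836, 0.197, 0.0641 and 0.0534. At 200 ng/ml AT1G72900 was higher by 2.58 ± 0.38 and AT4G38080 by 2.55 ± 0.32, and OCT1, AT4G29020 and AT5G45670 were lower by -4.76 ± 0.44, -4.71 ± 0.29 and -4.42 ± 0.37. In ckh1-1 OCT1 was near the floor at 25 ng/ml (1.72) and 200 ng/ml (1.11), as was AT5G45670 at 200 ng/ml (6.1). The sizes and ranks of these differences therefore depend on the pseudocount. Auxin response genes at 200 ng/ml had 3 of 6 lower, or 5 adjusted over the list alone, with GH3.1 at -1.98 ± 0.41 and WES1 at -1.88 ± 0.37 (camera adjusted p = 0.000121, adjusted p = 0.713 with an estimated correlation, and adjusted p = 0.0413 with an estimated correlation and the block). Both calls were lost without replicate 2 of ckh1-1 at 200 ng/ml (adjusted p = 0.192 and 0.133).

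Genes of the photosynthetic apparatus were among those higher in ckh2-1 than in the wild type over the 3 kinetin levels. Of 33 nuclear photosynthesis and chlorophyll genes 19 passed and all 19 were higher, 23 adjusted over the list alone and 26 with the block, with a median of 0.65 (6 arrays against 6). PSAE-1, a subunit of photosystem I, was higher by 2.16 ± 0.20, PORB, which reduces protochlorophyllide, by 1.84 ± 0.16, and PSBW, a subunit of photosystem II, by 1.67 ± 0.19. The photosynthesis list fixed beforehand had all 3 tested members higher, also 3 adjusted over the list alone: the antenna proteins LHCB4.1 (1.59 ± 0.20) and LHCB4.2 (1.22 ± 0.16) and RCA, the Rubisco activase (0.78 ± 0.19). Signals of LHCB4.1 were 1030 ± 159, 1060 ± 406 and 1300 ± 318 in ckh2-1 at 0, 25 and 200 ng/ml, against 303 ± 115, 356 ± 134 and 434 ± 164 in wild type. The camera call of the longer list (adjusted p = 2.14e-21) gave adjusted p = 0.288 with an estimated correlation and adjusted p = 0.0161 with an estimated correlation and the block. For the fixed list the values were 1.2e-05, adjusted p = 0.161 with an estimated correlation and adjusted p = 0.11 with an estimated correlation and the block. Without replicate 2 of wild type at 200 ng/ml, RCA was no longer called (adjusted p = 0.0517). Plastid-encoded photosynthesis genes had 5 of 46 higher, 6 adjusted over the list alone and 18 with the block, psbK among them by 0.77 ± 0.16 (camera adjusted p = 3.47e-07, and adjusted p = 0.303 with an estimated correlation).

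The largest differences in ckh2-1 were of other genes. AT1G58025 was higher by 3.19 ± 0.23 (1040 against 95.9), TBL41, of the wall acetylation family, by 3.00 ± 0.27, and the class III peroxidase AT4G30170 by 2.91 ± 0.24. AT3G23060 was higher by 2.85 ± 0.14 and the chitinase ChiC by 2.48 ± 0.29, and AT1G72900, AT2G45180 and AT1G62510 were higher by 2.31 to 2.42. The dirigent family gene AT4G11190 was lower by -3.76 ± 0.20 (16.4 against 566), AT2G16005 by -3.61 ± 0.19, AT3G63360 by -3.26 ± 0.34 and AT5G60530 by -3.16 ± 0.23. ZW9, AT5G38020, AT2G43860 and AT3G57620 had log2 fold changes from -2.65 to -2.33. All 16 stayed past the threshold under every alternative. XTH20 was lower by -1.62 ± 0.16, SWEET2 by -1.87 ± 0.21 and the defensin-like gene LCR68 by -1.83 ± 0.23. Of 6 auxin response genes, IAA29 was higher (0.75 ± 0.14) and LBD29 lower (-1.26 ± 0.25), 2 and 1 adjusted over the list alone, and camera gave adjusted p = 0.974.

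For ckh2-1 over the 3 levels limma called 757 probe sets higher and 787 lower, 774 of them mapping to 1 gene, with r = 0.801 between replicate numbers; the block called 1892 and 1929. Without kinetin the counts were 145 and 225 (block 479 and 736), at 25 ng/ml 184 and 127 (block 697 and 528) and at 200 ng/ml 300 and 350 (block 1029 and 1050). The totals with 1 array left out ran from 140 to 197, from 143 to 373 and from 271 to 431, lowest without replicate 2 of ckh2-1 without kinetin, replicate 1 of wild type at 25 ng/ml and replicate 1 of ckh2-1 at 200 ng/ml.

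The named genes of ckh2-1 at each level overlapped with those of the mean. Without kinetin TBL41 was higher by 3.84 ± 0.48 and AT1G58025 by 3.18 ± 0.40, and AT2G38870 by 3.33 ± 0.78, a call lost without replicate 2 of wild type (adjusted p = 0.285). AT3G63360, AT5G60530 and AT2G16005 were lower by -3.94 ± 0.58, -3.90 ± 0.40 and -3.73 ± 0.33. At 25 ng/ml AT4G30170 was higher by 3.31 ± 0.41, TBL41 by 3.11 ± 0.48, AT1G58025 by 2.89 ± 0.40 and AT3G23060 by 2.83 ± 0.24, and AT1G62510 and AT1G72900 by 2.64 ± 0.31 and 2.52 ± 0.38. AT4G11190 was lower by -3.91 ± 0.35, OCT1 by -3.55 ± 0.44 and AT2G16005 by -3.12 ± 0.33, and AT5G60530, AT2G43860 and AT1G69526 by -3.05 ± 0.40, -2.66 ± 0.46 and -2.43 ± 0.39. ChiC (2.65 ± 0.50), the peroxidase AT5G39580 (2.45 ± 0.47), AT3G63360 (-2.89 ± 0.58) and ZW9 (-2.47 ± 0.45) lost their calls with single arrays left out, with highest adjusted p of 0.128, 0.141, 0.129 and 0.0941. At 200 ng/ml AT3G23060 and ChiC were higher by 3.32 ± 0.24 and 3.13 ± 0.50 and AT1G58025 was also higher (1040 ± 128 against 70 ± 34.4), and OCT1, AT4G11190 and AT2G16005 lower by -4.50 ± 0.44, -4.10 ± 0.35 and -3.98 ± 0.33. OCT1 was near the floor in ckh2-1 at 25 and 200 ng/ml, so the sizes of its differences depend on the pseudocount. Nuclear photosynthesis and chlorophyll genes had 7, 7 and 15 of 33 higher at 0, 25 and 200 ng/ml, or 9, 16 and 16 adjusted over the list alone. Their camera calls were lost with adjusted p = 0.351, 0.438 and 0.143 with an estimated correlation.

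**Figure D3:**
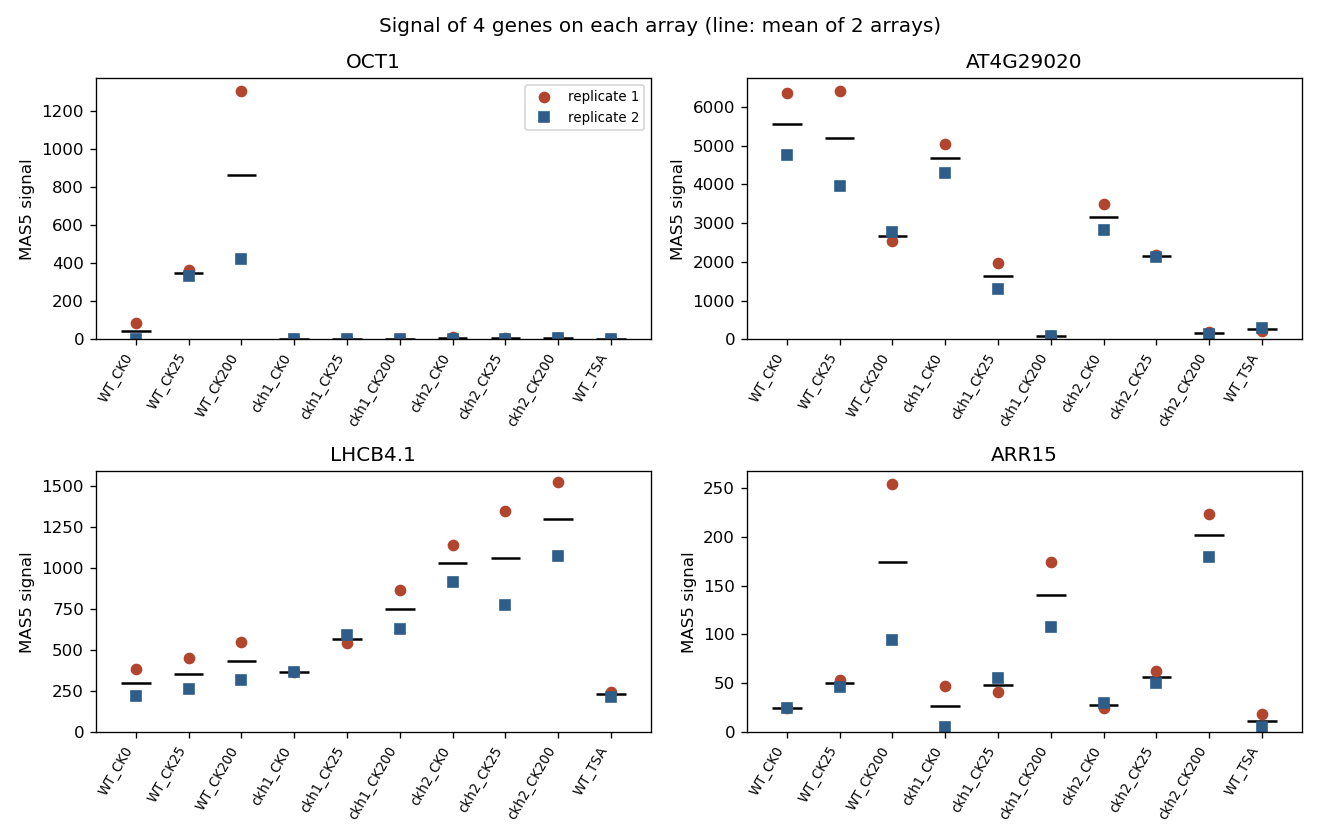
MAS5 signal of OCT1, AT4G29020, LHCB4.1 and ARR15 on each array by group, circles for replicate 1 and squares for replicate 2, with a line at the mean of both. At 200 ng/ml kinetin the mean signal of OCT1 was 865 in wild type, 1.11 in ckh1-1 and 6.78 in ckh2-1, and that of AT4G29020 was 2660, 75.4 and 160.

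TSA in place of kinetin raised AT2G43660 in wild type by 4.49 ± 0.28, from 34.4 ± 1.01 to 1380 ± 304. AT1G72900 rose by 3.68 ± 0.38, FDH, a formate dehydrogenase, by 3.38 ± 0.41 and the peroxidase AT4G30170 by 3.19 ± 0.41. AT1G21520, AT3G11150, AT2G25450 and AT2G43530 rose by 2.87 to 3.01. AT1G29090 fell by 5.11 ± 0.49, ZW9 by 4.68 ± 0.45, AT4G29020 by 4.29 ± 0.29, and AT2G43860 had a log2 fold change of -4.16 ± 0.46. AT5G60530, the peroxidase AT4G08780, AT5G12940 and AT3G26460 had log2 fold changes from -3.83 to -3.59. All 16 stayed past the threshold under every alternative.

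Some of the transcripts encoded in the plastid rose with TSA. Of 46 plastid-encoded photosynthesis genes 18 rose and 0 fell, 26 adjusted over the list alone and 33 with the block, with a median of 0.79. Among them petN and petG, of the cytochrome b6f complex, rose by 1.58 ± 0.23 and 1.56 ± 0.30. Of 19 plastid-encoded transcription and translation genes 8 rose, 11 adjusted over the list alone and 16 with the block, with a median of 0.81, rps4 by 1.21 ± 0.26 (adjusted p = 0.126 without replicate 1 of TSA). The camera calls (adjusted p = 1.22e-14 and 1.27e-07) both gave adjusted p = 0.157 with an estimated correlation. Nuclear photosynthesis and chlorophyll genes had 4 of 33 higher, also 4 adjusted over the list alone, and a median of 0.28 (camera adjusted p = 0.0443, and adjusted p = 0.876 with an estimated correlation). The ratio of 3' to 5' signal, which reads RNA quality, was 0.736 ± 0.0191 for GAPDH with TSA and 0.894 ± 0.192 without, and 5.57 ± 0.0919 and 5.78 ± 1.02 for actin.

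Among auxin response genes, IAA29 rose by 2.07 ± 0.25 and LBD16 by 1.12 ± 0.34 with TSA, 2 of 6, or 4 adjusted over the list alone (camera adjusted p = 0.0703). The LBD16 call was lost without replicate 1 of TSA (adjusted p = 0.179). BBM fell by 3.00 ± 0.31, scpl20 by 3.11 ± 0.36, GSTU20 by 2.51 ± 0.38 and XTH19 by 2.42 ± 0.35, while the glycosyltransferase UGT76B1 rose by 2.06 ± 0.28. Of the 3 genes of the fixed photosynthesis list RCA alone rose (1.11 ± 0.34), also 1 adjusted over the list alone, a call lost without replicate 1 of TSA (adjusted p = 0.332). limma called 903 probe sets higher and 793 lower with TSA, 886 of them mapping to 1 gene; the block called 2479 and 3008, with r = 0.8 between replicate numbers. The total was 736 without replicate 1 of TSA and 778 without replicate 1 of wild type without kinetin.

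Fold changes across the 15469 tested probe sets, which are not independent replicates, were then compared between contrasts that share no array. The TSA effect correlated with the ckh1-1 effect at 25 and 200 ng/ml with r = 0.458 (0.456 and 0.432 within replicates 1 and 2), and with the ckh2-1 effect with r = 0.431 (0.42 and 0.399). TSA and ckh1-1 shared 125 probe sets called higher, against 23.2 for independent calls, and 369 called lower, against 45.3, with 22 in opposite directions. With the block these were 614 against 254, 912 against 371, and 253, a smaller ratio of shared to independent calls. For TSA and ckh2-1 the numbers were 209 against 36.1, 240 against 27.4, and 25, and with the block 735 against 272, 707 against 314, and 261. AT1G72900, for example, was higher and AT2G43860 lower in TSA and in both mutants. The effects without kinetin, which share the wild type control with TSA, correlated with r = 0.214 and 0.285, and without replicate 2 of wild type without kinetin with r = 0.402 and 0.468. Sharing a control gave r = 0.5 in simulated data, so their covariances of 0.0657 and 0.0818 were set against simulated ones of 0.0227 and 0.0226. The simulation gave all groups the same spread per probe set. The replicates of wild type without kinetin correlated with r = 0.964, near the low end of the groups. The simulated covariances may therefore understate what the shared control alone gives.

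The response to 200 ng/ml correlated between ckh1-1 and wild type with r = 0.619 (0.631 and 0.392 within replicates) and between ckh2-1 and wild type with r = 0.702 (0.703 and 0.484). ckh1-1 and the wild type shared 214 probe sets called higher, against 13.5 for independent calls, and 133 lower, against 12.5, with 5 opposite, and with the block 705 against 127, 582 against 167, and 33. ckh2-1 and the wild type shared 203 against 10.3, 135 against 9.26, and 1 opposite, and with the block 691 against 102, 583 against 117, and 7. At 25 ng/ml r was 0.307 for ckh1-1 (0.175 and 0.277) and 0.277 for ckh2-1 (0.0739 and 0.253). These low-dose values rest on single wild type arrays: without replicate 2 of wild type at 25 ng/ml they were 0.035 and -0.037, and without replicate 1 of wild type without kinetin 0.081 and -0.043. The effect of ckh1-1 without kinetin correlated with that of ckh2-1 with kinetin at r = 0.304 (0.231 and 0.331), and the mirrored choice gave 0.421 (0.433 and 0.359). The mean effects, which share all wild type arrays, had r = 0.627, where sharing alone gave 0.5 in simulated data. Their covariance was 0.0967, against 0.00753 simulated with the same spread in all groups. They shared 209 probe sets called higher, against 20.8 for independent calls, and 490 lower, against 56.7, with 17 opposite, the independent numbers taking no account of the shared arrays. The block gave 791 against 219, 1030 against 263, and 140 opposite. AT3G63360, AT2G43860 and AT3G57620 were among those lower in both mutants.

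Gene lists were tested 418 times over all comparisons. Camera with its preset correlation called 132 of them, none of which held with the correlation estimated from the data (0 called by camera). Without the block that estimate includes the scaling difference between replicate numbers, so these failures do not decide whether a list changed. With the replicate block, an estimated correlation called 9, among them nuclear photosynthesis and chlorophyll genes in ckh2-1 and serine carboxypeptidase-like genes in ckh1-1. Rotation tests with fry called 25 without the block and 135 with it. The statements on single genes, such as LHCB4.1 or LBD29, do not rest on these list tests.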

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

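Of the tests in this part, those on the mirrored set of ckh1-1 were chosen only after the result was seen. The medians over the set of ckh2-1 and the mirrored set were taken on arrays rescaled to a common trimmed mean. That rescaling was also chosen after the data were seen.

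These results are listed because the responses of a mutant and the wild type to the same kinetin dose differed by the test of the difference itself. For ckh1-1 against wild type this held for 1 probe set at 25 ng/ml and for 189 at 200 ng/ml, and for ckh2-1 for 56 at 200 ng/ml. Genes with a higher response in ckh1-1 at 200 ng/ml were AT4G38080 (4.09), AT1G74460 (3.80) and AT2G23540 (3.76), and those with a lower one AT4G29020 (-4.46), AT5G45670 (-4.36) and AT5G01870 (-3.76). In ckh2-1 they were AT2G30540 (2.99), AT1G12080 (2.71) and psbT (2.11), and OCT1 (-3.67), AT4G17350 (-3.05) and AT4G29020 (-3.04). Higher and lower again give only the sign of the difference. AT4G29020 fell at 200 ng/ml in wild type and fell further in both mutants, so its lower response was a larger fall. OCT1 was near the floor in ckh2-1 at every level, so its value gives only a direction.

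The response to 25 ng/ml kinetin appeared in ckh1-1 with 299 calls and in wild type with 0, while the test of the difference called 1, and with the block these were 1471, 10 and 158 (84 differences after quantile normalization and 90 after rescaling). Over the 1280 probe sets of the ckh2-1 response to 200 ng/ml, the highest wild type median with 1 array left out was 0.31, against a lowest ckh1-1 median of 0.73, so a single wild type array that stood apart did not account for the gap. The difference between ckh1-1 and wild type at 25 ng/ml, which uses no array without kinetin, had a median of 0.37 in the lower of both replicates, against ckh1-1 arrays without kinetin that merely sat low. The interaction had a median of 0.55 in the lower replicate, to which lower ckh1-1 values without kinetin (a median difference of -0.11) contributed, and a larger low-dose response in ckh1-1 may explain the remainder, as a hypothesis found and tested on the same arrays. The difference at 200 ng/ml was 0.40, so the gap was not particular to the low dose. ARR15 had a difference in response of 0.04 at 25 ng/ml (adjusted p = 1). A difference between cultures, RNA quality and the share of the set that responds at all stay open. In ckh1-1 at 0 and 25 ng/ml the ratio of 3' to 5' signal was 4.06 ± 0.686 and 4.95 ± 0.156 for actin. For GAPDH it was 0.964 ± 0.122 and 0.704 ± 0.126. In wild type these were 5.78 ± 1.02 and 6.7 ± 2.27, and 0.894 ± 0.192 and 0.812 ± 0.0445.

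For ckh2-1 the mirrored set, the 1699 probe sets of the ckh1-1 response to 200 ng/ml, gave a median response to 25 ng/ml of 0.37 (0.43 and 0.32 within replicates 1 and 2), against 0.17 in wild type (0.16 and 0.18). The median difference between these responses was 0.22 (0.26 and 0.16). The levels at 25 ng/ml differed between ckh2-1 and wild type by 0.31 in replicate 1 and -0.02 in replicate 2, and those without kinetin by 0.08 and -0.18. Whether ckh2-1 arrays without kinetin that sat low enlarged the response was therefore left open. For the difference in response limma called 0 single probe sets, and 1 with the block. At an unadjusted p below 0.05 there were 178, fewer than chance alone would give, and 888 with the block.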

How the results depend on the processing

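The rescaling of all arrays to a common trimmed mean, the block together with 1 array left out and the list tests with the replicate block were tests chosen only after the result was seen, and the other alternatives were set before.

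Among the counts, correlations and list results, 251 of the alternative values stayed on the same side of their threshold and within the limits for their kind, 128 moved, 10 weakened, 4 strengthened and 2 reversed. The block raised every count of a comparison. By construction it removes the scaling difference between replicate numbers from the spread, as quantile normalization and rescaling do, but rescaling called fewer than the block, and the cause of the remainder was not tested. With the block, limma called 10 probe sets in wild type at 25 ng/ml and 1764 at 200 ng/ml, 1471 and 5145 in ckh1-1, and 146 and 3847 in ckh2-1. Against wild type it called 1407, 1509 and 2265 in ckh1-1 at 0, 25 and 200 ng/ml and 3898 over the levels, 1215, 1225 and 2079 in ckh2-1 and 3821 over the levels. The differences in response numbered 158 and 820 for ckh1-1 and 1 and 269 for ckh2-1 at 25 and 200 ng/ml, and TSA had 5487.

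Nothing in the labels says what a replicate number marks. The deviations of same-numbered arrays from their group means were correlated across probe sets over the 45 pairs of groups. After rescaling r ran from -0.12 to 0.63 with a median of 0.16, and 26 pairs exceeded 0.1. On deposited values it ran from -0.13 to 0.64, with 27 pairs above 0.1. Most but not all pairs deviated together, so the numbers were not taken to pair the samples, and a shared structure beyond the scaling was not excluded.

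Quantile normalization gave 1384 in wild type at 200 ng/ml, 1208 and 4048 in ckh1-1, and 93 and 3104 in ckh2-1. Against wild type it gave 1112, 1223 and 1734 in ckh1-1 and 3373 over the levels, and 928, 984 and 1748 in ckh2-1 and 3321 over the levels. The differences in response were 84 and 551 for ckh1-1 and 191 for ckh2-1 at 200 ng/ml, and TSA had 4627. Rescaled arrays gave, in the same order, 1374, then 1162 and 4350, then 107 and 3221. Against wild type they gave 1120, 1180, 1818 and 3312 for ckh1-1, and 969, 927, 1736 and 3303 for ckh2-1. Differences in response were 90, 585 and 206, and TSA had 4654.

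Without a filter on dim probe sets more were tested, and ckh2-1 at 25 ng/ml had 3 calls, the difference in response of ckh1-1 at 25 ng/ml 0 and ckh2-1 against wild type at 25 ng/ml 189. The correlation of TSA with ckh1-1 was then 0.434 and with ckh2-1 0.408. With the smaller pseudocount, ckh2-1 at 25 ng/ml had 33 calls and the difference in response of ckh1-1 at 25 ng/ml 0, and the cause was not tested. Of 418 list tests, camera with an estimated correlation called 0 and fry 25, against 132, and 112 to 141 with 1 array left out.

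With 1 array left out, which leaves fewer arrays and the scaling unbalanced, wild type had 0 to 1 calls at 25 ng/ml and 148 to 367 at 200 ng/ml. ckh1-1 had 68 to 129 and 1030 to 1183, and ckh2-1 0 to 7 and 727 to 879. Against wild type ckh1-1 had 158 to 303, 61 to 273 and 279 to 443 at 0, 25 and 200 ng/ml and 1231 to 1506 over the levels. For ckh2-1 these were 140 to 197, 143 to 373, 271 to 431 and 1262 to 1507. Differences in response were 0 to 3 and 111 to 212 for ckh1-1, and 0 to 1 and 15 to 83 for ckh2-1, and TSA had 736 to 1574. The correlation of TSA ran from 0.365 to 0.521 with ckh1-1 and from 0.341 to 0.491 with ckh2-1, and from 0.173 to 0.402 and from 0.236 to 0.468 with the shared control. Between mutant and wild type responses to 200 ng/ml it ran from 0.493 to 0.654 for ckh1-1 and from 0.551 to 0.725 for ckh2-1. At 25 ng/ml it ran from 0.035 to 0.414 for ckh1-1 and from -0.043 to 0.443 for ckh2-1, where it reversed without replicate 1 of wild type without kinetin (-0.043) and without replicate 2 of wild type at 25 ng/ml (-0.037). Between the mutant effects it ran from 0.233 to 0.363, from 0.322 to 0.450 in the mirrored choice and from 0.613 to 0.642 for the means.

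Of 509 results on single genes, all of them calls of the main fit, all kept their side of the threshold with the block. Every probe set called without the block was also called with it, so this is no separate support for these genes. Calls were lost in 4 with rescaled arrays, 5 with quantile normalization, 19 with the smaller pseudocount and 82 without the filter, and in 741 values with 1 array left out, where 2359 kept theirs, and none reversed. The signal over background limits what can be said of dim transcripts: 7277 probe sets were not tested, and fold changes against signals as low as those of OCT1 in the mutants depend on the pseudocount. With 2 arrays per group, a change of 1 on the log2 scale was recovered for 20 of 100 simulated probe sets, and for 81 with the block, so an absent call does not show an absent change.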

Other observations

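The medians of the plastid transcripts within replicates, the splits on rescaled arrays and the mirrored set under TSA were tests chosen only after the result was seen.

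OCT1 stayed near the floor of the measurement in both mutants, with mean signals of 1.41, 1.72 and 1.11 in ckh1-1 and 6.26, 4.67 and 6.78 in ckh2-1 at 0, 25 and 200 ng/ml, where wild type had 45.1 ± 58.8, 348 ± 20.3 and 865 ± 625. Wild type with TSA (2.27 ± 1.13) and replicate 2 of wild type without kinetin (3.56) were as low. On rescaled arrays, probe sets of the ckh1-1 response to 200 ng/ml had a median of 0.46 under TSA when signed by that response (0.57 and 0.35 within replicates 1 and 2). AT4G29020 followed this, with 259 ± 56.1 under TSA against 5560 ± 1140 without.

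Plastid-encoded transcripts had a median log2 fold change of 0.81 with TSA over 65 genes in the fit with the block. With the actin and GAPDH ratios as covariates the median was again 0.81 (quartiles 0.45 and 1.09), while calls went from 49 to 40. Over all probe sets the covariates changed the fold change by a median of 0.07 in absolute size. Both ratios differed between wild type with TSA and without kinetin by less than their SD without kinetin. Adjusting for them could therefore hardly move the median, and RNA quality was not excluded. The medians within replicates were 0.62 and 0.92, which could not test the scaling of the arrays, as every group holds 1 array of each scaling. A higher level of plastid RNA under TSA may be a response to the treatment, as a hypothesis, and a change in the share of plastid RNA carried into labelling was not tested.

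The arrays of each mutant and the wild type were also divided in other ways within the kinetin levels, with 100 of the 108 possible splits drawn. Each split was fitted on these 12 arrays alone with the kinetin level, so the counts differ from the 1540 and 1544 of the fit of all arrays. For ckh1-1, 2 of 100 splits called as many probe sets as the real one, itself included: the real split called 1354 and the highest other 7306. That split follows the replicate numbers, which carry the scaling difference, and without it the highest other was 196. On rescaled arrays the real split called 2426 and the highest other 12, again the split by replicate number, with 8 as the highest without it. For ckh2-1 the count was also 2 of 100, with 1446 for the real split, 7291 for the split by replicate number and 1 without that split. On rescaled arrays the real split called 2641, against 85 for the split by replicate number and 1 without that split. For ckh2-1 a structure of the replicate numbers thus remained after rescaling. With 2 of 100 splits for either mutant, a chance division of these 12 arrays is an unlikely source of its difference from the wild type. The labels do not say that the arrays are separate cultures. Chance was therefore not excluded, nor was a difference between cultures of the genotypes.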
